A study of Rattus norvegicus with 42 samples.

How the data were processed

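Lung RNA from 42 male Fischer 344 rats was sequenced, 19 rats sampled 3 months and 23 sampled 9 months after a whole-body inhalation exposure to crystalline silica or to air. The rats ate a regular diet with 18% of its energy as fat or a high-fat diet with 60%, and the silica groups breathed 15 mg per cubic metre for 6 hours a day on 5 days. Libraries were stranded total RNA libraries from which ribosomal RNA had been depleted. The authors deposited 1 table per time point that holds raw read counts per gene symbol, with 1 column per rat, so the unit of every value used is counts, per the deposited tables and their labels. The processing notes of the submitters name bcl2fastq 2.19, Trimmomatic 0.35, TopHat2 2.0.9, Bowtie2 2.2.9, SAMtools 0.1.19, HTSeq 0.6.1 and the rat genome build Rnor_6.0. They do not state the strand setting of the counting or the source of the gene annotation, so counts of genes that overlap on opposite strands, and of near-identical gene copies, are uncertain. No coordinates are given, since the annotation at hand belongs to a later build.

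Each table held 30045 gene symbols, of which 30044 were shared. All values were whole numbers. Total counts per library ran from 5143424 to 8259635 at 3 months and from 3078216 to 8319382 at 9 months. Counts of any 2 libraries differed by more than counting error, with a chi-square per degree of freedom over genes with at least 10 counts of at least 1.93 in the 91 pairs within a group and 2.69 in the 770 pairs between groups, so no column was a copy or a split of another. The Y-linked gene Kdm5d had at least 251 counts in every library. Rats are numbered within their group in the order of their tags. Tags were not shared between groups, so no pairing was used, and the labels gave no batch or date. Each time point was sequenced from its own rats and stored in its own table, so time, age and table are 1 factor. Silica effects were compared across time only as differences of differences.

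Before the data were examined, 12 tests, 38 gene lists and the rule for named genes were fixed. Genes were kept by the filterByExpr rule of edgeR 4.0.16 on the groups, which left 15234 genes at 3 months, 15276 at 9 months and 15759 in both tables together. Library sizes were scaled by TMM (trimmed mean of M values). Quasi-likelihood models were fitted with edgeR in R 4.3.3 (legacy=FALSE), with 1 coefficient per group and the 4 groups of a time point in 1 fit. Each fit tested silica minus air on each diet, high-fat minus regular diet under each exposure, and the difference between the silica effects on the 2 diets (the interaction). The difference between the silica effects at 9 and 3 months was tested on each diet in 1 fit of all 8 groups. A gene was called when its Benjamini-Hochberg adjusted p was below 0.05. Log2 fold changes are given with the standard error implied by the quasi-likelihood F statistic, and levels are in CPM (read counts relative to the TMM-scaled library size) with the standard deviation (SD) between rats. The option legacy=FALSE was fixed as the default, but the installed version has the other setting as its default, and it was run as an alternative.

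Gene lists with at least 5 tested members were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated from each list. Of the 544 genes in the lists, 520 were present in both tables, and no listed symbol of a gene encoded by mitochondrial DNA was found. Other symbols for such genes were not searched. Named genes are the 8 with the largest rise and the 8 with the largest fall in each silica or diet comparison (mean log2 CPM of at least 1, no placeholder symbol, no immunoglobulin or T cell receptor segment), the 4 members with the smallest p of each list described, a fixed panel of 14 genes, and for each interaction or time difference the 6 genes with the smallest adjusted p in each direction. A gene that the rule would name is not reported here and was left out without replacement. Where a group had 1 to 3 counts in all, levels replace the fold.

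The tests were tried on simulated counts with the group sizes and spreads of the real libraries. Between 2.5% and 7.25% of the calls were false, and the share of genes recovered at a simulated change of 2-fold was 77.6% for silica on the regular diet at 3 months and 93.9% at 9 months, and 95.4% and 87.9% on the high-fat diet. For the interaction it was 74.2% at 3 months and 80.6% at 9 months. A list with a simulated shift was called in every comparison and none of 20 lists without a shift was called. The simulated genes were drawn independently of each other, so this does not test calls of lists whose members rise and fall together.

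Alternatives fixed in advance were RLE (relative log expression) size factors, no filter on low counts, the DESeq2 1.42.0 Wald test, limma voom with sample weights, a fit of other sets of groups, and leaving out each rat in turn. Alternatives chosen after seeing the data were the legacy dispersion fit, the log2 share of counts on Rnr1 and Rnr2 as a covariate, and the fits without regular-diet air rat 3 (liver transcripts) or high-fat silica rat 2 (fewest counts) of 9 months, which are 2 of the fits that leave out 1 rat. Rnr1 and Rnr2 carry ribosomal RNA symbols. Their identity rests on the symbol alone, because neither is in the annotation at hand, and the tables do not show whether they are mitochondrial or nuclear. Their summed share of a library is called the ribosomal RNA share. It was compared between groups by two-sided exact permutation tests of the mean log2 share, adjusted over 8 tests. Each count of calls was also recomputed for 100 splits of the same rats, the real one included. For the time differences, the other splits were fitted with an added term for the time of sampling. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.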

Results

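Gene expression was measured by RNA sequencing in whole lung of 42 male rats in 8 groups. At 3 months after exposure there were 4 rats on the regular diet in air, 5 on the regular diet with silica, 5 on the high-fat diet in air and 5 on the high-fat diet with silica. At 9 months the same groups held 6, 5, 6 and 6 rats. Total counts per rat ran from 3078216 to 8319382, and the range of each time point overlapped the other's. The series asks what part a high-fat diet plays in the lung toxicity of silica. The comparisons below give the silica effect on each diet, the diet difference under each exposure, the difference between the 2 silica effects, and the change of the silica effect with time.

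The ribosomal RNA share of the libraries (the counts on Rnr1 and Rnr2) differed between groups at 9 months. It was 1.22% ± 0.70 (SD, n = 6) in air and 3.67% ± 1.07 (n = 5) with silica on the regular diet, and 6.21% ± 1.11 (n = 6) in air and 7.66% ± 0.22 (n = 6) with silica on the high-fat diet. The exact permutation tests of all 4 comparisons of 9-month groups gave adjusted p between 0.00577 and 0.00866. At 3 months the group means lay between 0.957% and 1.26%, with adjusted exact permutation p of 0.254 to 0.286. Every 9-month comparison below therefore moves with this share as well as with its own factor.

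**Figure D1:**
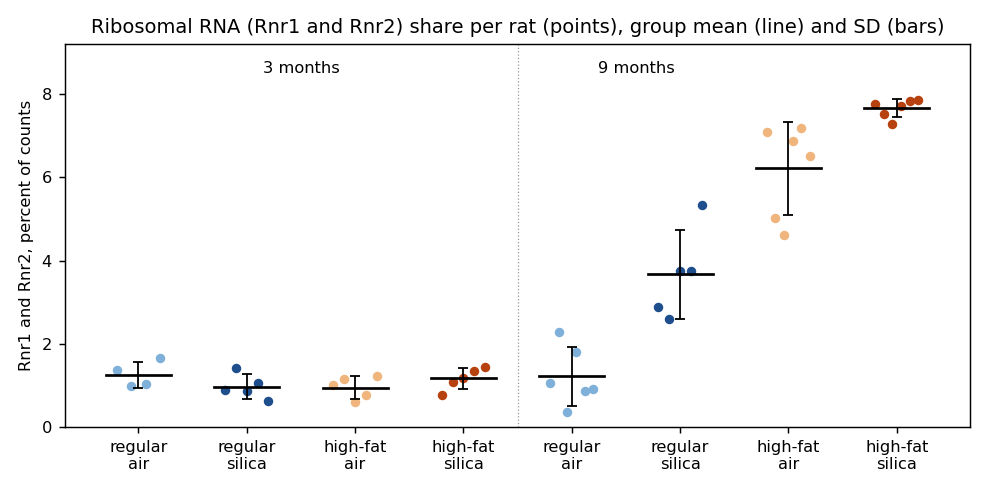
Ribosomal RNA share (Rnr1 and Rnr2, percent of all counts of a library) for each rat as a point, with the group mean as a line and the SD as bars. The 9-month means rise from 1.22% in regular-diet air rats to 7.66% in high-fat silica rats, and the 3-month means all lie below 1.3%.

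**Figure D2:**
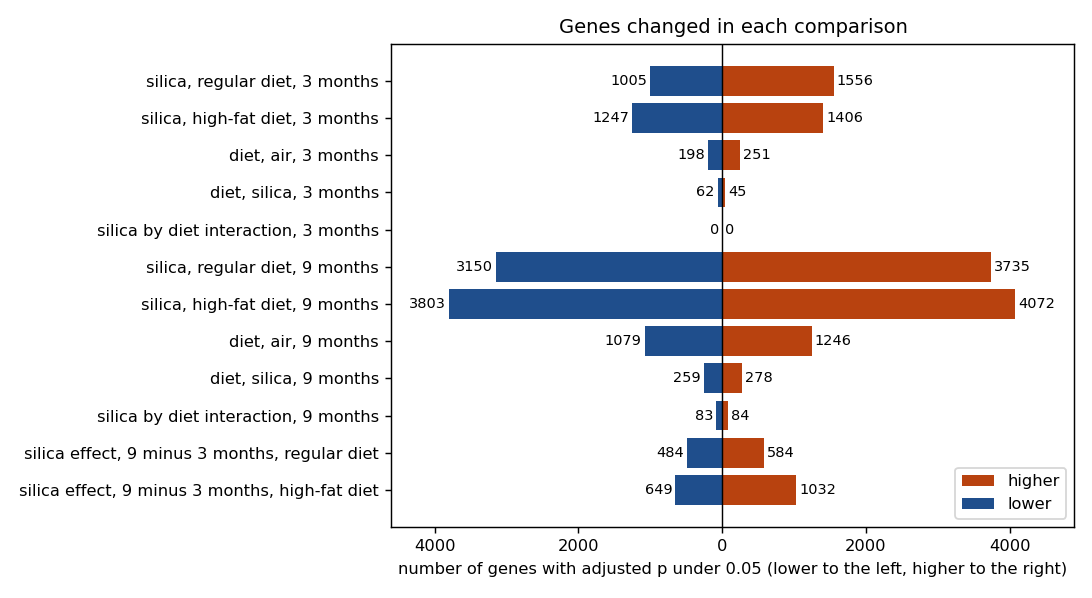
Number of genes called higher and lower in each comparison. Silica on the high-fat diet at 9 months has the most calls, 7875, and the interaction at 3 months has 0.

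Silica on the regular diet at 3 months raised genes of innate defence and neutrophil recruitment. Lcn2, an iron-binding antimicrobial protein, was at 73.7 ± 7.1 CPM (SD, n = 5) with silica and 8.04 ± 2.26 CPM (n = 4) in air, a log2 fold change of 3.20 ± 0.18 (SE, adjusted p = 3.9e-11). The chemokines Cxcl6 and Ccl2, which attract neutrophils and monocytes, rose by 4.09 ± 0.24 and 3.06 ± 0.24 on the log2 scale. Mmp12, an elastase made by macrophages, rose by 3.11 ± 0.17, and complement C3 by 1.91 ± 0.10 (adjusted p = 7.9e-12). Spp1, which encodes osteopontin, rose by 2.81 ± 0.50 (adjusted p = 4.8e-04).

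In all, 2561 of 15234 genes were called, 1556 higher and 1005 lower, and 244 of them differed at least 2-fold, 214 higher and 30 lower. Among the largest rises were Slc26a4, the anion exchanger pendrin (4.02 ± 0.30), Cd177, a neutrophil surface protein (3.40 ± 0.17), Tmem45b, Fstl4, Vat1l and C2cd4b. Lpo, which encodes lactoperoxidase, stood at 0.12 CPM in air, from 3 counts in all, and 4.66 CPM with silica. The largest fall was in Dlk1, a Delta-like membrane protein, at 5.49 CPM in air and 0.0588 CPM with silica, from 2 counts in all. Kcnmb2 (-1.66), Sytl5 (-1.62), Tesc (-1.41), Cldn8 (-1.10), Ucp3 (-1.05) and Alox15 (-1.02) also fell. Surfactant genes Sftpc and Sftpd rose by 0.60 and 0.56. Col1a1, the main chain of type I collagen, was not called (0.11 ± 0.14, adjusted p = 0.62), nor were the club cell gene Scgb1a1 (-0.46, adjusted p = 0.082) and Pdk4 (-0.63, adjusted p = 0.052). Of the 105 called genes of the naming rule, all 5 silica rats lay beyond the air mean for 105 and beyond every air rat for 98. These genes were picked for their calls in the same rats, so this tally, like those below, describes the rats and is not separate support.

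By gene list, 12 of 16 acute-phase and antimicrobial genes rose and 0 fell (camera adjusted p = 5.7e-34), 13 when adjusted over the list alone, with Chi3l1 at 1.77 ± 0.08 and S100a9 at 2.70 ± 0.21. For complement, 12 of 19 rose (3.5e-17), 14 adjusted over the list alone, among them Cfb, C1qc and C1qb. Of 18 genes of lipid-laden macrophages 13 rose and 1 fell (5.4e-17), 13 and 2 adjusted over the list alone, with Lgals3, Fabp5 and Ctsk between 1.26 and 1.37. Of 21 chemokines 12 rose (2.7e-16), of 9 class II antigen presentation genes 7 rose (1.3e-14), with Cd74 at 0.76 ± 0.08, and of 12 alveolar type 2 cell genes 10 rose (1.9e-14), with Lamp3 at 0.80 ± 0.09. Adjusted over the list alone these counts were 13, 8 and 10. Cell cycle genes rose in 13 of 17 (1.8e-10), 14 adjusted over the list alone, with Mki67 at 0.94 ± 0.10. Neutrophil genes rose in 6 of 7 (7.9e-10) and alveolar macrophage genes in 6 of 10 with 1 fall (5.6e-08), the same counts when adjusted over the list alone. The calls of these 9 lists held with an estimated correlation.

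Other lists were called with the preset correlation only. Lipogenesis rose in 9 of 16 genes (adjusted p = 5.5e-07, and adjusted p = 0.12 with an estimated correlation), and oxidative stress response in 9 of 21, with Sod2 at 1.52 ± 0.10 (3.7e-06, and adjusted p = 0.24 with an estimated correlation). Endothelial genes fell in 8 of 12, with Tek at -0.36 ± 0.06 (7.9e-07, and adjusted p = 0.075 with an estimated correlation), and alveolar type 1 cell genes in 7 of 10, with Rtkn2 at -0.47 ± 0.07 (2.4e-05, and adjusted p = 0.079 with an estimated correlation). Fibroblast genes fell in 4 of 10 (0.001, and adjusted p = 0.12 with an estimated correlation). Adjusted over the list alone, these counts were 11, 10, 8, 7 and 4. Cholesterol synthesis, inflammasome and cytokine, plasma cell and dendritic cell genes were called higher and ciliated cell genes lower, and their adjusted p were between 0.062 and 0.62 with an estimated correlation. The extracellular matrix list, with 4 of 25 genes higher and 5 lower, was not called (adjusted p = 0.96).

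On the high-fat diet at 3 months, Mmp12 stood at 49.3 ± 5.7 CPM with silica and 2.15 ± 0.61 CPM in air (n = 5 each), a log2 fold change of 4.48 ± 0.19 (adjusted p = 2.2e-13). Lcn2 rose by 4.18 ± 0.21, Cxcl6 by 4.70 ± 0.31, Ccl2 by 3.57 ± 0.24, C3 by 2.35 ± 0.09 and Spp1 by 3.23 ± 0.49. The Spp1 air mean of 1.92 CPM depends on rat 4, without which it is 1.18 CPM. Slc26a4, Cd177 and Tmem45b rose by 4.42, 4.39 and 4.00. Vat1l had 3 counts in all in air rats, so no fold is given for it. Sftpc and Sftpd rose by 0.64 and 0.66, and Scd, the desaturase that makes oleate, by 0.42. Cyp1a1, a monooxygenase induced through the aryl hydrocarbon receptor, fell by 0.95 ± 0.22 (adjusted p = 0.0036), and Pdk4, a brake on glucose oxidation, fell by 0.69 (adjusted p = 0.015). Npr3 (-1.45), Mlc1 (-1.42), Alox15 (-1.31) and Ass1 (-1.20) fell, and Dlk1 had 2 counts in all with silica. Col1a1 was not called (0.26, adjusted p = 0.17).

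Here 2653 genes were called, 1406 higher and 1247 lower, with 236 higher and 31 lower at least 2-fold. All 5 silica rats lay beyond the air mean for all but 1 of the called genes of the naming rule and beyond every air rat for 81.6%. Acute-phase and antimicrobial genes rose in 11 of 16 (camera adjusted p = 1.9e-37), complement in 14 of 19 (2.4e-24), class II antigen presentation in 9 of 9 (2.4e-21), lipid-laden macrophages in 12 of 18 with 1 fall (3.9e-20) and chemokines in 10 of 21 (1.1e-16). Alveolar type 2 cell genes rose in 10 of 12 (2.9e-14), cell cycle genes in 11 of 17 and alveolar macrophage genes in 6 of 10 with 1 fall (3.3e-11 each). Adjusted over the list alone, 12, 18, 9, 12, 12, 10, 13 and 7 members of these 8 lists rose, and all 8 calls held with an estimated correlation. Endothelial genes fell in 9 of 12, 9 adjusted over the list alone (5.9e-08, and adjusted p = 0.058 with an estimated correlation). Erythroid genes, of which the haemoglobin genes are near-identical copies, fell in 6 of 8, 8 adjusted over the list alone (6e-07, and adjusted p = 0.061 with an estimated correlation). Neutrophil genes rose in 3 of 7, 4 adjusted over the list alone (6.1e-06, and adjusted p = 0.058 with an estimated correlation).

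Across all 15234 genes, the silica log2 fold changes on the 2 diets at 3 months had Pearson r = 0.717, and genes are not independent replicates. The 2 comparisons share no rat. Of the calls, 981 genes were higher on both diets where 143.6 would be shared by independent lists, 523 were lower on both where 82.3 would be, and 1 was called in opposite directions.

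**Figure D3:**
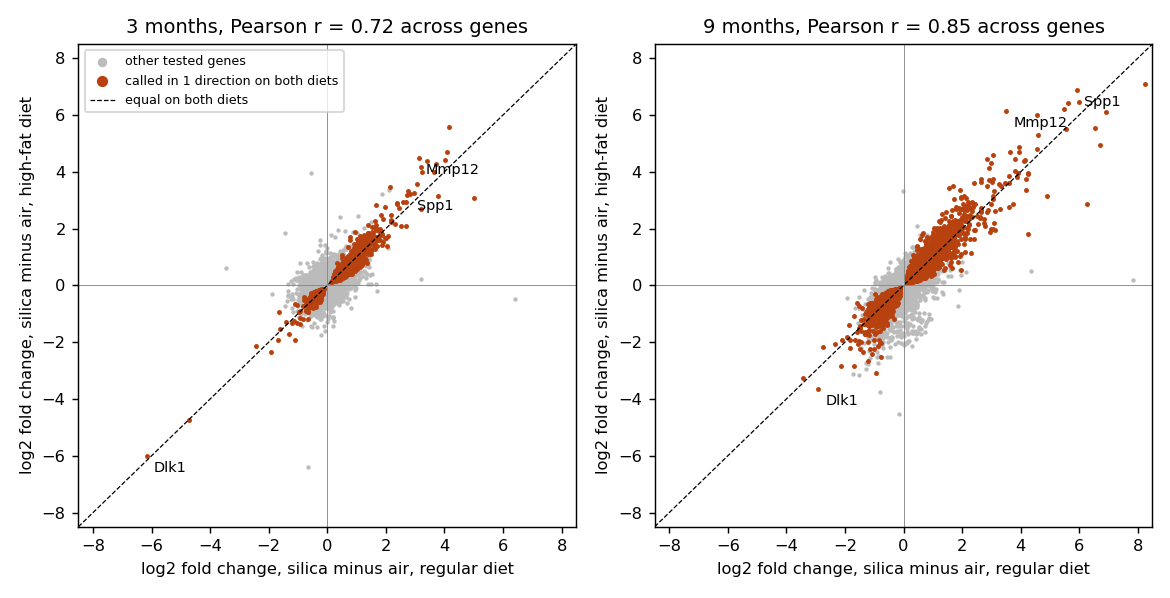
Log2 fold change of silica over air for each tested gene on the regular diet (horizontal axis) and on the high-fat diet (vertical axis), at 3 and 9 months. Pearson r across genes is 0.717 at 3 months and 0.850 at 9 months.

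Diet in air at 3 months changed few genes by much, and Cyp1a1 most. It stood at 53.5 ± 19.1 CPM (SD, n = 5) on the high-fat diet and 0.555 CPM (n = 4) on the regular diet, a log2 fold change of 6.53 ± 0.49 (adjusted p = 6.6e-08). Nr1d1, a repressor in the circadian clock, rose 4.55-fold (adjusted p = 1.7e-04) and Acot1, an acyl-CoA thioesterase with near-identical copies, by 3.15 ± 0.49 on the log2 scale (adjusted p = 0.0031). Lower on the high-fat diet were Lcn2 by -1.75 ± 0.31 (adjusted p = 0.0066), Mmp12 by -1.42 ± 0.30 (adjusted p = 0.017), Cxcl1 by -1.11 ± 0.19, Cxcl2 by -1.78 ± 0.36 and C3 by -0.71 ± 0.09 (adjusted p = 4.9e-04). Trem2, a lipid receptor of macrophages (-1.18 ± 0.17), and Atp6v0d2, a proton pump subunit (-2.31 ± 0.43), fell.

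Alveolar macrophage genes fell in 4 of 10, 6 adjusted over the list alone (camera adjusted p = 3.1e-08, and adjusted p = 0.12 with an estimated correlation), and lipid-laden macrophage genes in 4 of 18, 8 adjusted over the list alone (3.9e-06, and adjusted p = 0.35 with an estimated correlation). Cholesterol synthesis genes rose in 4 of 19, 6 adjusted over the list alone, with Srebf2, the master regulator of sterol synthesis, at 0.28 ± 0.06 (1.9e-06, and adjusted p = 0.3 with an estimated correlation). Lipogenesis genes rose in 2 of 16, 6 adjusted over the list alone, with the regulator Srebf1 at 0.50 ± 0.11 (1.1e-04, and adjusted p = 0.44 with an estimated correlation). Complement fell in 2 of 19, 5 adjusted over the list alone (4.4e-04, and adjusted p = 0.3 with an estimated correlation), and acute-phase and antimicrobial genes in 3 of 16, 3 adjusted over the list alone (0.0017, and adjusted p = 0.3 with an estimated correlation). Chemokines fell in 2 of 21, with 3 falls and 1 rise adjusted over the list alone (0.0085, and adjusted p = 0.44 with an estimated correlation). The aryl hydrocarbon receptor list was called higher (1.4e-04, and adjusted p = 0.028 with an estimated correlation), though Cyp1a1 was the only member of 8 to rise. The clock list, with 4 of 16 genes higher, was not called (adjusted p = 0.15).

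Of 15234 genes 449 were called, 251 higher and 198 lower, 45 of them at least 2-fold. All 5 high-fat rats lay beyond the regular-diet mean for all 45 called genes of the naming rule and beyond every regular-diet rat for 37, but leaving out 1 rat ended the call of 32 of the 45. The count rests on single rats and on the test: leaving out regular-diet rat 2, 3 or 4 left 29.8%, 28.7% or 14% of the calls, and leaving out high-fat rat 1, 3 or 4 left 55.9%, 29.0% or 45.0%. The count was 730 with DESeq2, 956 with limma voom, 761 in a fit of these 2 groups only, and 93 with the ribosomal RNA share as a covariate, where all 449 kept their sign, the median size of the log2 fold change went from 0.389 to 0.357 and the median SE from 0.0931 to 0.0982.

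Diet with silica at 3 months again raised Cyp1a1 most, to 27.3 ± 11.4 CPM from 0.443 CPM (n = 5 each), a log2 fold change of 5.95 ± 0.50 (adjusted p = 5.3e-07). Clock genes rose with it: Dbp, a clock output regulator, by 2.38 ± 0.34 (adjusted p = 7.3e-04), Nr1d1 by 1.92 ± 0.20 (adjusted p = 2.6e-05), Per3 by 1.47 ± 0.21, Nr1d2 by 1.24 ± 0.15 and Cry2 by 0.61 ± 0.07. Aqp3, a water and glycerol channel, rose 4.01-fold. Cxcl6 (-1.09 ± 0.15), Lcn2 (-0.76 ± 0.12, adjusted p = 0.0028), Cxcl1 (-0.65 ± 0.14) and Ctsk, a lysosomal protease (-0.82 ± 0.13), fell.

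Clock genes rose in 7 of 16 and fell in 2, 7 and 6 adjusted over the list alone (camera adjusted p = 1.9e-06), and this call and that of the aryl hydrocarbon receptor list (8.7e-04, 1 of 8 higher) held with an estimated correlation. Cholesterol synthesis genes rose in 3 of 19, 14 adjusted over the list alone, with Sqle at 0.47 ± 0.09 (1.2e-13, and adjusted p = 0.058 with an estimated correlation). Alveolar macrophage genes fell in 4 of 10, 7 adjusted over the list alone, with Itgax at -0.55 ± 0.09 (2.2e-08, and adjusted p = 0.065 with an estimated correlation). Lipogenesis genes rose in 2 of 16, 6 adjusted over the list alone (5e-07, and adjusted p = 0.2 with an estimated correlation). In total 107 genes were called, 45 higher and 62 lower, and all 5 high-fat rats lay beyond the regular-diet mean for all 38 called genes of the naming rule and beyond every regular-diet rat for 35. Leaving out 1 rat ended the call of 13 of the 38. The count was 209 without regular-diet rat 3, 69 without regular-diet rat 4, 55 without high-fat rat 2 and 60 without high-fat rat 3. It was 227 with DESeq2, 59 in a fit of these 2 groups only, and 169 with the ribosomal RNA share as a covariate.

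The interaction at 3 months asks whether the silica effect differs between diets. With edgeR 0 genes were called and 990 had an unadjusted p below 0.05. DESeq2 called 1 gene and limma voom 0. The silica effect on Mmp12 was larger on the high-fat diet by 1.37 ± 0.32 on the log2 scale (adjusted p = 0.49), that on Lcn2 by 0.98 and that on C3 by 0.44 (adjusted p = 0.74 each). Erythroid genes were called lower as a list (camera adjusted p = 1.9e-05, and adjusted p = 0.82 with an estimated correlation), with 0 of 8 members called. Ciliated cell, neutrophil, extracellular matrix and B cell lists were called too, with 0 members called in each and adjusted p of 0.82 to 0.87 with an estimated correlation.

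With silica on the regular diet at 9 months, Spp1 reached 265 ± 59.2 CPM (SD, n = 5) from 4.43 ± 3.17 CPM in air (n = 6), a log2 fold change of 5.92 ± 0.34 (adjusted p = 6.7e-13). Retnla, a marker of alternatively activated macrophages, rose by 5.62 ± 0.26, Ccl2 by 3.63 ± 0.23, Mmp12 by 3.51 ± 0.33, C3 by 2.11 ± 0.11 and Lcn2 by 1.94 ± 0.16. Hmox1, the haem-degrading enzyme of the oxidative stress response, rose by 1.90 ± 0.07 (adjusted p = 6.8e-16). Col1a1 was not called (-0.05, adjusted p = 0.74). The ribosomal RNA share was 3.67% with silica and 1.22% in air.

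Lpo rose by 8.23 ± 0.44, Tmem72 by 5.98, Scn10a by 5.53 and Rasgrf1 by 4.90. Cpne5 stood at 0.0584 CPM in air, from 2 counts, and 8.99 CPM with silica. C4a-2, a complement C4 symbol whose near-identical copies cannot be told apart with certainty, had 0 counts in 6 air rats and 13.0 ± 12.2 CPM with silica. Dlk1 (-2.91), Kcnmb2 (-2.34), Sh2d7 (-1.84), Fbp1 (-1.70), Tesc (-1.66) and Sytl5 (-1.58) fell. Sftpd and Angptl4 rose by 0.78 and 0.70, and Sftpc was not called (0.20, adjusted p = 0.14).

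Complement rose in 17 of 19 genes, 17 adjusted over the list alone, with C4b at 1.99 ± 0.11 and Cfi at 3.05 ± 0.20 (camera adjusted p = 9.9e-18). Acute-phase and antimicrobial genes rose in 15 of 18 (1.1e-13), class II antigen presentation in 7 of 8 (3e-11), cell cycle genes in 16 of 17 with Mki67 at 1.66 ± 0.11 (3.2e-10), chemokines in 18 of 23 with 3 falls (1.7e-08) and oxidative stress genes in 12 of 21 with 3 falls (3.2e-07). Adjusted over the list alone, 17, 7, 16, 18 and 12 rose. These 6 calls held with an estimated correlation. Lipid-laden macrophage genes rose in 14 of 18 with 2 falls, 15 and 3 adjusted over the list alone (2.7e-08, and adjusted p = 0.094 with an estimated correlation). Alveolar macrophage genes rose in 9 of 11 with 1 fall, 9 and 1 adjusted over the list alone (3.2e-07, and adjusted p = 0.062 with an estimated correlation). Endothelial genes fell in 11 of 12, 11 adjusted over the list alone (1.1e-06, and adjusted p = 0.17 with an estimated correlation), and fibroblast genes in 8 of 10, 8 adjusted over the list alone, with Pdgfra at -0.64 ± 0.09 (4.7e-04, and adjusted p = 0.094 with an estimated correlation). Lists of alveolar type 2 cells, cholesterol synthesis, lipogenesis, neutrophils, plasma cells, and inflammasome and cytokine genes were called higher and that of alveolar type 1 cells lower, with adjusted p of 0.053 to 0.35 with an estimated correlation. In the matrix list 7 of 25 genes rose, 14 fell and the list was not called (adjusted p = 0.15).

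Of 15276 genes 6885 were called, 3735 higher and 3150 lower, 738 of them at least 2-fold. All 5 silica rats lay beyond the air mean for 143 of the 147 called genes of the naming rule and beyond every air rat for 81.0%. With the ribosomal RNA share as a covariate the count was 3870, while 6858 of the 6885 kept their sign. The median size went from 0.456 to 0.458 and the median SE from 0.0929 to 0.150. The shares with silica (2.60% to 5.35%) and in air (0.375% to 2.29%) did not overlap, so that adjustment extrapolates a slope within groups.

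Silica on the high-fat diet at 9 months gave the most calls of all comparisons. Spp1 stood at 307 ± 69.4 CPM with silica and 2.97 ± 3.69 CPM in air (n = 6 each), a log2 fold change of 6.90 ± 0.35 (adjusted p = 3.2e-14). The air mean depends on rat 6, at 10.5 CPM, as the other 5 had a mean of 1.47 CPM. Mmp12 stood at 136 ± 15.1 and 2.11 ± 1.94 CPM, a log2 fold change of 6.14 ± 0.39, and was also highest in that air rat, at 5.89 CPM against a mean of 1.35 CPM in the other 5. Retnla rose by 6.43, Slc26a4 by 5.99 ± 0.29, Ccl2 by 4.69 ± 0.24, Lcn2 by 3.37 ± 0.18 and C3 by 2.80 ± 0.11. Scd rose by 0.83 ± 0.07, Sftpc by 0.78 and Sftpd by 1.18. Col1a1 (-0.35 ± 0.09, adjusted p = 0.0033), Cyp1a1 (-1.72 ± 0.20), Pdk4 (-0.57) and Scgb1a1 (-0.44) fell. The ribosomal RNA share was 7.66% with silica and 6.21% in air.

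Among the largest falls were Mb, Myl3, Ckm and Myh7, genes of striated muscle (-3.16, -3.12, -2.77 and -2.74), and Upk3b, a mesothelial gene (-3.07). Relative to the raw total count, without TMM scaling, levels of the cardiac myosin gene Myh6 ran from 0.162 to 355 CPM between single rats of the whole series. The mesothelial list fell in 6 of 8 genes with 1 rise, 6 and 1 adjusted over the list alone (camera adjusted p = 0.019, and adjusted p = 0.5 with an estimated correlation). The cardiac muscle list, with 6 of 10 lower, was not called (adjusted p = 0.23).

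Complement rose in 18 of 19 genes (2.1e-19), lipid-laden macrophages in 14 of 18 with 2 falls (1.8e-14) and acute-phase and antimicrobial genes in 15 of 18 (4e-13). Alveolar macrophage genes rose in 10 of 11 with 1 fall (5.5e-12), class II antigen presentation in 7 of 8 (1.5e-11), chemokines in 18 of 23 with 3 falls (5.2e-10) and alveolar type 2 cell genes in 10 of 12 with 1 fall (2.1e-09). Lipogenesis rose in 15 of 17, with Fasn at 1.27 ± 0.11 (3.3e-09), and cholesterol synthesis in 18 of 19, with Cyp51 at 0.90 ± 0.07 (1e-08). Adjusted over the list alone, 18, 14, 15, 10, 8, 18, 10, 15 and 18 members of these 9 lists rose. These calls held with an estimated correlation, as did those of the cell cycle, oxidative stress, plasma cell, and inflammasome and cytokine lists. Endothelial genes fell in 12 of 12, 12 adjusted over the list alone (1.3e-06, and adjusted p = 0.16 with an estimated correlation), and fibroblast genes in 9 of 10, 9 adjusted over the list alone (2.8e-04, and adjusted p = 0.061 with an estimated correlation). In the matrix list 6 genes rose, 16 fell and the list was not called (adjusted p = 0.067). In all 7875 genes were called, 4072 higher and 3803 lower, with 733 higher and 322 lower at least 2-fold. With the ribosomal RNA share as a covariate the count was 7734 and all 7875 kept their sign. The median size went from 0.475 to 0.479 and the median SE from 0.0906 to 0.0936. Here too the shares with silica (7.29% to 7.85%) and in air (4.62% to 7.19%) did not overlap, so the adjustment extrapolates. All 6 silica rats lay beyond the air mean for 153 of the 154 called genes of the naming rule and beyond every air rat for 125.

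Between the diets, the 9-month silica effects had Pearson r = 0.850 across 15276 genes. Of the calls, 2941 genes were higher on both diets (995.6 expected of independent lists), 2484 were lower on both (784.2) and 20 were called in opposite directions.

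**Figure D4:**
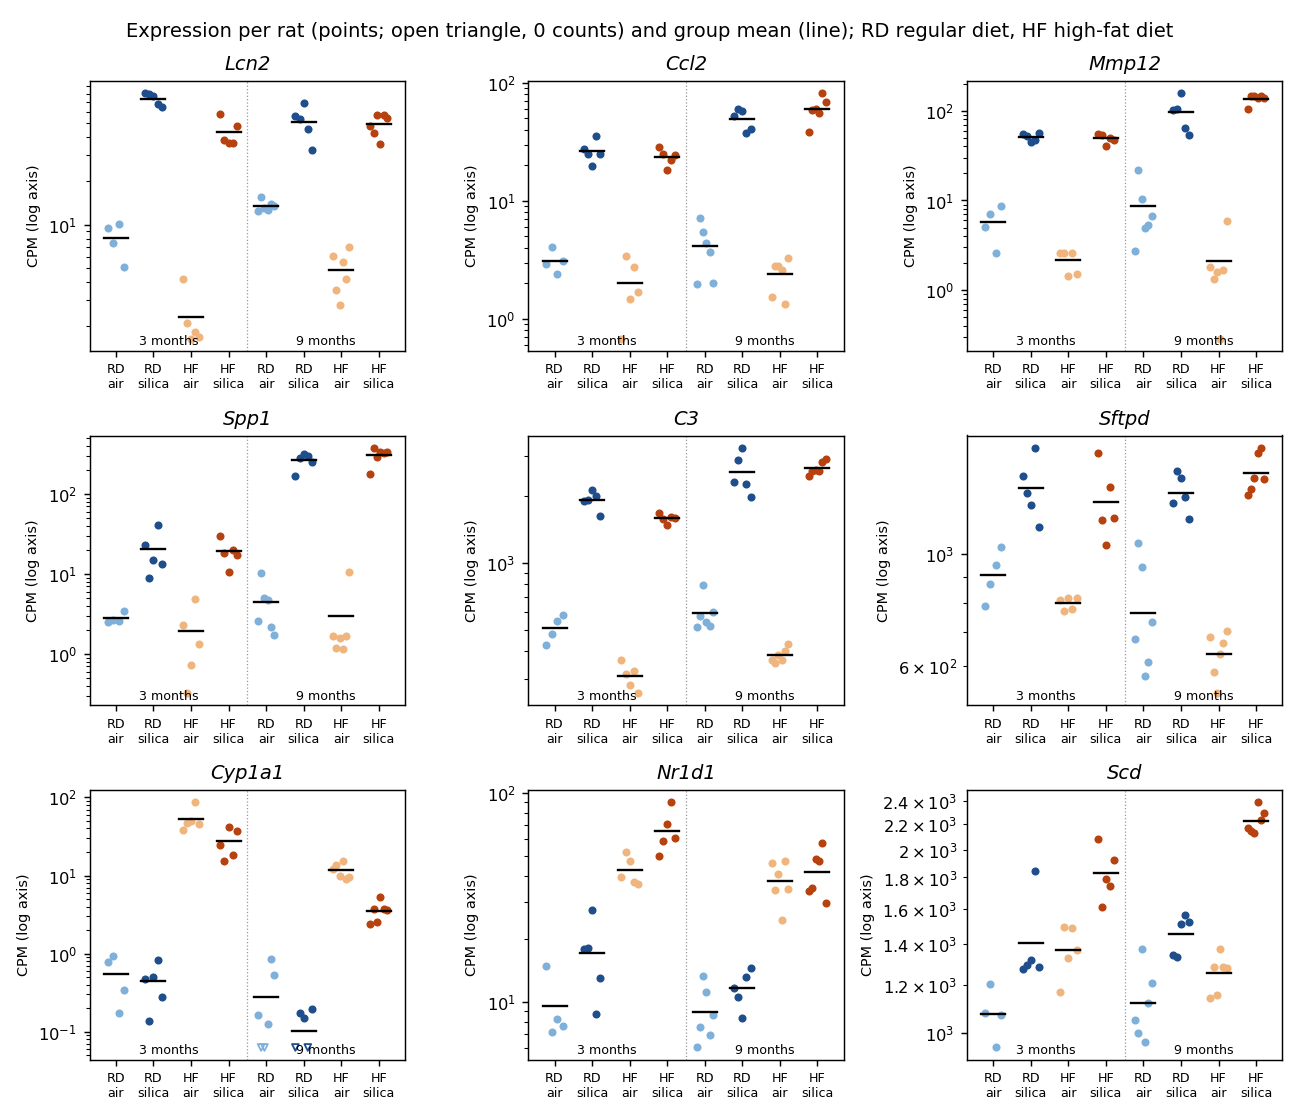
Level of 9 genes in each rat (points, CPM on a log axis, open triangles for 0 counts) by group, with the group mean as a line. By group mean, Spp1 and Mmp12 are highest in the 9-month silica groups, and Cyp1a1 and Nr1d1 are higher on the high-fat diet in every pair of groups.

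Diet in air at 9 months again raised Cyp1a1, to 11.6 ± 2.59 CPM from 0.282 CPM (SD, n = 6 each; 0.165 CPM without regular-diet rat 5), a log2 fold change of 5.30 ± 0.31 (adjusted p = 5.7e-14), and Nr1d1 by 2.09 ± 0.19 (adjusted p = 3.7e-07). Lower on the high-fat diet were Trem2 by -1.40 ± 0.14 (adjusted p = 7.2e-07), Mmp12 by -2.14 ± 0.51 (adjusted p = 0.0051), Atp6v0d2 by -2.03 ± 0.33 and Gpnmb by -0.85 ± 0.11. Lcn2 (4.87 ± 1.6 against 13.5 ± 1.12 CPM, adjusted p = 2.3e-05), Cxcl1 (-0.73), C3 (-0.63) and Ch25h (-1.77 ± 0.20), an enzyme that hydroxylates cholesterol, also fell. Col1a1 rose by 0.34 (adjusted p = 0.014) and Scgb1a1 by 0.55. Rnr1 and Rnr2 rose by 2.91 and 2.26, and the ribosomal RNA share was 6.21% against 1.22%.

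Lipid-laden macrophage genes fell in 11 of 18, 12 adjusted over the list alone (camera adjusted p = 1.8e-13, and adjusted p = 0.094 with an estimated correlation), and alveolar macrophage genes in 8 of 11, 9 adjusted over the list alone (1.5e-09, and adjusted p = 0.094 with an estimated correlation). Complement fell in 6 of 19 with 1 rise, 11 and 1 adjusted over the list alone (4.1e-04, and adjusted p = 0.14 with an estimated correlation). Oxidative stress genes fell in 10 of 21 with 2 rises, 12 and 2 adjusted over the list alone (0.0019, and adjusted p = 0.24 with an estimated correlation). Clock genes rose in 5 of 17 and fell in 2, 6 and 3 adjusted over the list alone (0.031, and adjusted p = 0.13 with an estimated correlation). Of the 91 called genes of the naming rule, all 6 high-fat rats lay beyond the regular-diet mean for 89 and beyond every regular-diet rat for 50, and leaving out 1 rat ended the call of 11. C4a-2, with near-identical copies, had 0 counts on the regular diet and 4.93 ± 1.95 CPM on the high-fat diet.

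Of 15276 genes 2325 were called, 1246 higher and 1079 lower, 78 of them at least 2-fold. With the ribosomal RNA share as a covariate 1 gene was called, while 2212 of the 2325 kept their sign. The median size of the log2 fold change went from 0.318 to 0.223 and its median SE from 0.0782 to 0.171, so that the share and the diet can hardly be told apart in these rats. Under that covariate Rnr1 (-0.86) and Sqle (-0.05) turned negative and Fasn (0.02) turned positive.

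Diet with silica at 9 months raised genes of sterol and fatty acid synthesis. Scd rose by 0.62 ± 0.07 (adjusted p = 2.1e-05), Fads2, a desaturase, by 0.76 ± 0.07 (adjusted p = 8.8e-07) and Sqle, squalene epoxidase, by 0.52 ± 0.09 (adjusted p = 0.0020). Nr1d1 rose by 1.85 ± 0.20 (adjusted p = 3.4e-06). Cyp1a1 stood at 3.56 ± 1.06 CPM (n = 6) on the high-fat diet and 0.103 CPM, from 3 counts in all, on the regular diet (n = 5). Zbtb16, a transcription factor induced by glucocorticoids, fell by 1.76 ± 0.15 (adjusted p = 2.3e-07), from 182 ± 37 to 54.0 ± 9.36 CPM. Mesothelial genes Upk3b, Wt1, Upk1b and Lrrn4 fell (-2.39, -2.26, -1.68 and -1.63), as did Slc26a3, an anion exchanger (-3.18).

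Cholesterol synthesis genes rose in 7 of 19, 13 adjusted over the list alone (camera adjusted p = 4.5e-14), and lipogenesis genes in 7 of 17, 9 adjusted over the list alone (2e-13). Glucocorticoid response genes fell in 3 of 12, 8 adjusted over the list alone (1.3e-08), with Tsc22d3 at -0.55 ± 0.12 and Fkbp5 at -0.85 ± 0.20. Clock genes rose in 5 of 17, with 7 rises and 3 falls adjusted over the list alone (6.2e-04). These 4 calls held with an estimated correlation. Mesothelial genes fell in 6 of 8, 6 adjusted over the list alone (1.4e-06, and adjusted p = 0.18 with an estimated correlation). Of the 40 called genes of the naming rule, all 6 high-fat rats lay beyond the regular-diet mean for 39 and beyond every regular-diet rat for 26, and leaving out 1 rat ended the call of 19. The ribosomal RNA share was 7.66% against 3.67%.

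In this comparison 537 genes were called, 278 higher and 259 lower, 28 at least 2-fold. The count was 260 without regular-diet rat 2, 354 without regular-diet rat 3, 321 without high-fat rat 3, 350 without high-fat rat 4, 262 without high-fat rat 5 and 331 without high-fat rat 6. With the ribosomal RNA share as a covariate 27 were called, while all 537 kept their sign, the median size went from 0.346 to 0.297 and the median SE from 0.0807 to 0.104.

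The interaction at 9 months compares the 2 silica effects. Lcn2, Mmp12 and C3 had a larger silica effect on the high-fat diet in their rise, by 1.43 ± 0.25 (adjusted p = 0.0055), 2.63 ± 0.58 (adjusted p = 0.026) and 0.69 ± 0.15 (adjusted p = 0.026). With silica Lcn2 was at 51.3 ± 13.4 (n = 5) on the regular and 49.0 ± 8.33 CPM (n = 6) on the high-fat diet, Mmp12 at 96.1 ± 40.4 and 136 ± 15.1 CPM, and C3 at 2545 ± 534 and 2667 ± 186 CPM. In air Lcn2 was at 4.87 ± 1.6 CPM on the high-fat and 13.5 ± 1.12 CPM on the regular diet (n = 6 each). Mmp12 in air ran from 2.77 to 22.0 CPM on the regular diet, with rat 2 highest and the next at 10.4 CPM. On the high-fat diet it ran from 0.290 to 5.89 CPM. C3 in air ran from 513 to 797 CPM on the regular and 353 to 429 CPM on the high-fat diet. Gpnmb and Trem2, genes of lipid-handling macrophages, differed by 0.90 ± 0.16 and 1.07 ± 0.19, and Scd by 0.45 ± 0.10. Between single rats, Trem2 ran from 37.6 to 71.6 CPM on the regular and 15.1 to 25.4 CPM on the high-fat diet in air. With silica it ran from 62.6 to 81.0 and 53.6 to 64.6 CPM. In the same diet order, Gpnmb ran from 389 to 620 and 245 to 352 CPM in air. With silica it ran from 1524 to 2018.5 and 1426 to 2090 CPM. Scd ran from 967 to 1372 and 1141 to 1375 CPM in air, and from 1333 to 1564 and 2132 to 2392 CPM with silica. Zbtb16 differed by -1.95 ± 0.21 (adjusted p = 1.3e-05), with a silica log2 fold change of -0.088 ± 0.15 on the regular diet (adjusted p = 0.655) and -2.04 ± 0.15 on the high-fat diet (adjusted p = 2.1e-11).

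Lipid-laden macrophage genes were higher in 6 of 18, 9 adjusted over the list alone (camera adjusted p = 2.2e-11), lipogenesis genes in 4 of 17, 11 adjusted over the list alone (1.1e-10), and alveolar macrophage genes in 2 of 11, 5 adjusted over the list alone (5e-08). Each of these had adjusted p = 0.1 with an estimated correlation. Mesothelial genes were lower as a list with 0 of 8 called (0.0071, and adjusted p = 0.57 with an estimated correlation). The ribosomal RNA share had an interaction of its own of -1.44 on the log2 scale.

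In total 167 genes were called, 84 higher and 83 lower, and 2175 had an unadjusted p below 0.05. Among regular-diet rats, the count was 103 without air rat 2, 274 without air rat 4, 88 without silica rat 4 and 72 without silica rat 5. Among high-fat rats it was 90, 104 and 85 without air rats 1, 2 and 3, and 273, 108, 80 and 107 without silica rats 1, 3, 5 and 6. It was 348 with DESeq2, 264 with limma voom and 23 with the ribosomal RNA share as a covariate, where all 167 kept their sign, the median size went from 0.523 to 0.479 and the median SE from 0.115 to 0.143.

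The silica effect changed with time on both diets. On the regular diet Esr1, the oestrogen receptor, was at 83.1 ± 24.8 CPM with silica (n = 5) and 6.88 CPM in air (n = 6) at 9 months, and at 7.30 (n = 5) and 6.08 CPM (n = 4) at 3 months, a difference of 3.35 ± 0.30 (adjusted p = 1.4e-09). Fabp4, a fatty acid carrier of macrophages and fat cells, differed by 2.11 ± 0.27 and Spp1 by 3.10 (adjusted p = 0.016). Lcn2 had a smaller effect at 9 months, by -1.27 ± 0.27 (adjusted p = 0.0029). On the high-fat diet Esr1 differed by 3.49 ± 0.28 (adjusted p = 1.9e-11), Chia, an acidic chitinase, by 3.12, Spp1 by 3.67 (adjusted p = 0.0045) and the complement gene C4b, which has near-identical copies, by 1.85 ± 0.19. Col3a1 and Col1a1, collagen genes, differed by -0.58 ± 0.07 (adjusted p = 9e-07) and -0.61 (adjusted p = 0.012).

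Complement genes gained with time in 7 of 19 on the regular diet, 9 adjusted over the list alone (camera adjusted p = 2.9e-05, and adjusted p = 0.19 with an estimated correlation), and in 8 of 19 on the high-fat diet, 9 adjusted over the list alone (8.4e-08), where the call held. Lipid-laden macrophage genes gained in 9 of 18 on the high-fat diet, 13 adjusted over the list alone (1.6e-08, and adjusted p = 0.2 with an estimated correlation). Matrix genes lost in 10 of 25 and gained in 2 on the high-fat diet, 13 and 5 adjusted over the list alone (4.3e-04, and adjusted p = 0.24 with an estimated correlation). The list's mean log2 fold change, 0.02, has the opposite sign to its median, -0.24.

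Of 15759 genes 1068 were called on the regular diet, 584 higher and 484 lower, and 1681 on the high-fat diet, 1032 higher and 649 lower. The first count was 667 without regular-diet air rat 4 of 3 months, 471 in a fit of its 4 groups only and 77 with the ribosomal RNA share as a covariate, and the second was 1115 without high-fat silica rat 3 of 3 months. Under the covariate 1067 of the 1068 kept their sign, the median size went from 0.486 to 0.431 and the median SE from 0.123 to 0.161.

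**Figure D5:**
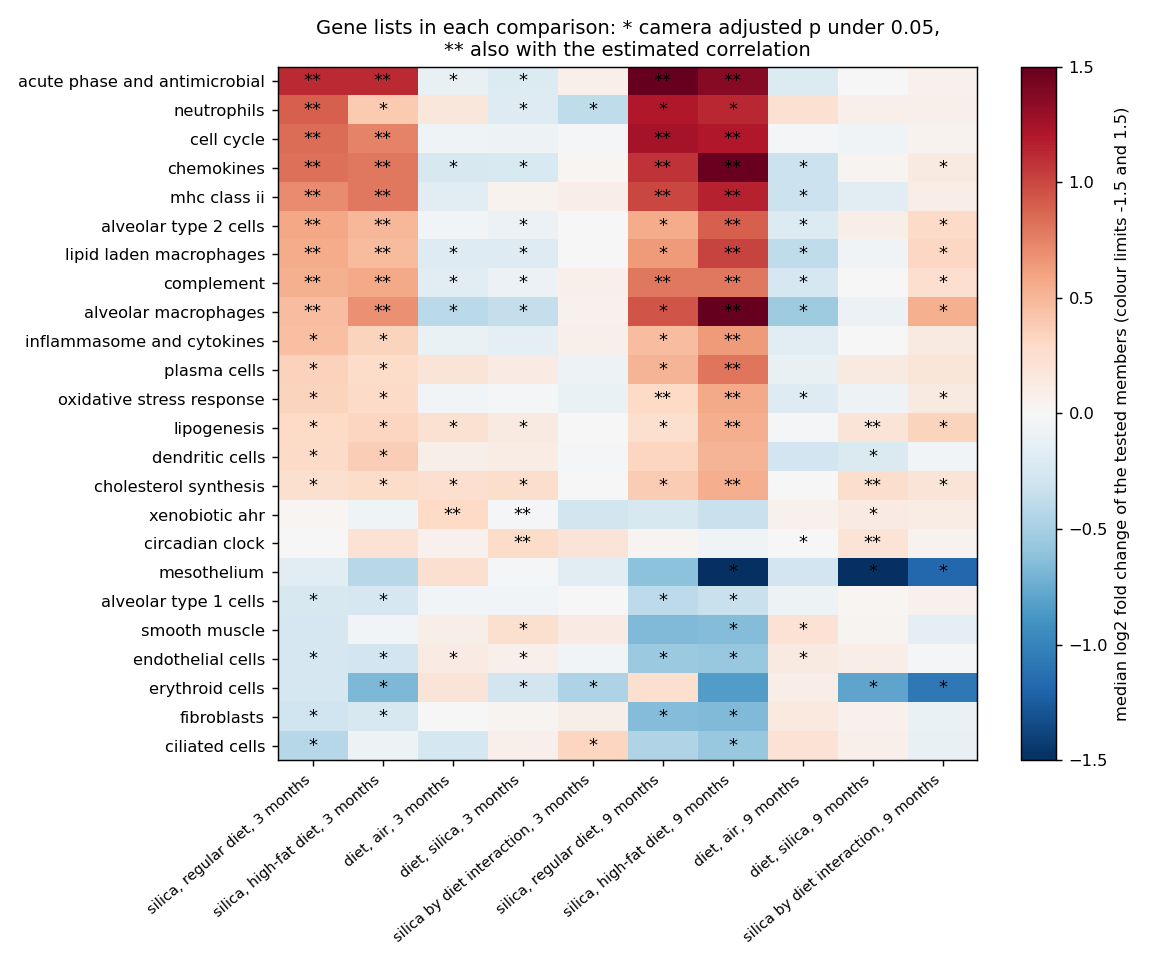
Median log2 fold change of each gene list (rows) in each comparison (columns), for lists called in at least 3 of 10 comparisons, with 1 star for a camera adjusted p below 0.05 and 2 stars where the call also holds with an estimated correlation. Complement and acute-phase lists are higher with silica in all 4 silica comparisons.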

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

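All tests of explanations in this part, the splits of the rats included, were chosen after the results were seen. Of 152 pairs of a group and a measure, 14 held a rat far from the rest of its group by a gap test, where chance would give 7.6. Rats are numbered within their group. Genes detected were 18797 in silica rat 4 on the regular diet at 3 months, where the next lowest rat had 19219, and 19335 in high-fat air rat 1 at 3 months, where the next highest had 18905. Relative to the raw total count, without TMM scaling, liver transcripts summed to 1886 CPM in regular-diet air rat 3 at 9 months (next 357), and 333 in high-fat silica rat 1 at 9 months (next 255). C3 was also highest in that regular-diet air rat, at 797 CPM (next 600). Lcn2 was at 4.22 CPM in high-fat air rat 1 at 3 months (next 2.11). Spp1 was at 3.41 CPM in regular-diet air rat 4 at 3 months (next 2.65) and at 10.5 CPM in high-fat air rat 6 at 9 months (next 1.70). That last rat also had the highest Mmp12 of its group, 5.89 CPM (next 1.84). High-fat silica rat 1 at 9 months had the lowest Mmp12 of its group, 106 CPM, and the highest Pdk4, 15.4 CPM (next 10.9). Angptl4 was at 14.6 CPM in high-fat silica rat 1 at 3 months (next 9.83), Cyp1a1 at 86.8 CPM in high-fat air rat 4 at 3 months (next 50.5), and Scd at 1844 CPM in regular-diet silica rat 4 at 3 months (next 1320).

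The silica effect differed between diets at 9 months for 167 genes by the test of the interaction. The 6 with the smallest adjusted p and a higher silica log2 fold change on the high-fat diet were Cxcr1 (1.06 on the log2 scale), a neutrophil chemokine receptor, Hk3 (0.96), a hexokinase, Gpnmb (0.90), Naaa (0.88), Capn5 (0.48) and Flvcr2 (0.40). The 6 with a lower log2 fold change on the high-fat diet were Zbtb16 (-1.95; -0.088 on the regular and -2.04 on the high-fat diet), Zfp366 (-0.88), Khdrbs1 (-0.65), Rcsd1 (-0.52), Tardbp (-0.51) and Hnrnpa3 (-0.35), of which Khdrbs1, Tardbp and Hnrnpa3 encode RNA-binding proteins.

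Between 3 and 9 months the silica effect differed for 1068 genes on the regular diet and 1681 on the high-fat diet, by tests of the difference. On the regular diet the 12 named genes were Esr1 (3.35), Fabp4 (2.11), Ncf1 (1.47), a subunit of the phagocyte oxidase, Col16a1 (1.15), Hhip (0.92) and Tmtc1 (0.81), and in the other direction Kifc2 (-0.89), Gpt (-0.81), Lpl (-0.70), Mxra8 (-0.65), Pxdc1 (-0.63) and Cadps2 (-0.49). On the high-fat diet they were Esr1 (3.49), Chia (3.12), C4b (1.85), Ncf1 (1.45), Col16a1 (1.27) and Tmtc1 (0.89), and in the other direction Adamts17 (-1.08), Mamdc2 (-0.88), Slc7a10 (-0.86), Ltbp1 (-0.75), Aoc3 (-0.64) and Col3a1 (-0.58).

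The diet difference in air at 9 months went with a higher ribosomal RNA share on the high-fat diet. If that share were the cause, genes that follow it among 3-month rats should follow the 9-month difference. The correlation across 2305 called genes was 0.275, and 5 of 100 permutations of the shares, the real order included, reached as far. This goes the way the share predicts but lies on the limit of the test and not past it, so the test cannot tell. Of genes called at both times 126 went in 1 direction and 28 in opposite directions, but the share of 0.957% against 1.26% at 3 months was not shown to differ (adjusted exact permutation p = 0.254), so this does not exclude the share. Diet and the ribosomal RNA content of the libraries may each account for the difference, and with the share as a covariate 1 gene was called.

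Nr1d1, Nr1d2 and Per3 were called higher on the high-fat diet in all 4 comparisons, while the clock list was not called in air at 3 months (adjusted p = 0.15) and lost its call in air at 9 months with an estimated correlation (adjusted p = 0.13). With the ribosomal RNA share as a covariate all 3 stayed called at 3 months (lowest log2 fold change 1.14), which argues against the share as their whole cause there. At 3 months, though, the share was not shown to differ between diets (adjusted exact permutation p = 0.254 in air and 0.286 with silica), so the covariate had little to remove. With silica at 9 months all 3 stayed called too (lowest 0.65). There the shares of the regular and high-fat diets did not overlap (2.60% to 5.35% against 7.29% to 7.85%). That adjustment extrapolates a slope within groups and cannot exclude the share. In air at 9 months their calls ended as the SE widened (Per3 from 0.60 ± 0.11 to 0.73 ± 0.25), so there it stays open. A later or earlier hour of tissue collection would move the opposing genes Arntl, Clock, Npas2 and Cry1 as well. Their median over the 4 comparisons was -0.214, with 3 of 16 values called lower and 1 called higher. Called lower were Arntl (-0.79) and Npas2 (-0.59) with silica at 3 months and Cry1 (-0.37) in air at 9 months. Npas2 was called higher (0.40) in air at 9 months. The hour may differ from group to group, so the median does not settle it for single comparisons. The labels do not give the hour, so it could still contribute, as could an effect of the diet on the clock.

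At 9 months the silica log2 fold change was called higher on the high-fat diet for 6 of 18 lipid-laden and 2 of 11 alveolar macrophage genes, and neither list was called with an estimated correlation (adjusted p = 0.1 each). For the ribosomal RNA content, the correlation across 164 genes was -0.330 and 14 of 100 permutations, the real order included, reached as far, which leaves it open. For the share of alveolar macrophages in the tissue, all 11 markers were above 0 with a median of 0.531, but these markers are part of the pattern itself, so this share is left open too. The genes with a higher interaction had a median diet difference of -0.37 in air and 0.12 with silica. For those with a lower interaction the medians were 0.42 in air and -0.074 with silica. In both directions the diets differed more in air, where diet and the ribosomal RNA share can hardly be told apart. A higher interaction can thus come from lower levels in high-fat air rats. Bulk RNA cannot separate a change in the number of macrophages from a change in expression per cell, in air or with silica.

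Each count of calls was compared with 100 splits of the same rats, the real one included. For silica at 3 months 1 split reached the real count on each diet, the real one, and the highest other counts were 2428 of a real 2561 on the regular diet and 765 on the high-fat diet. For diet at 3 months it was 1 split each, with highest other counts of 32 in air and 16 with silica. At 9 months it was 1 split each for silica (highest others 5234 on the regular and 4626 on the high-fat diet) and for diet (1544 in air and 342 with silica). No other split reached these 8 counts, so chance is an unlikely source of them. With 100 splits, and a test chosen after the results were seen, chance is not excluded. The highest others came mostly from splits that nearly mirror the real groups. For the interaction at 3 months the real count was 0, which all 100 splits reach by construction, so the splits say nothing. For the interaction at 9 months 2 splits reached the real count, the highest with 425, and the next highest other split had 1. The split with 425 moved 10 of 12 air rats but 2 of 11 silica rats. It nearly reversed the diets in air and nearly kept them with silica, so 425 holds the diet differences and does not measure chance. For the time difference on the regular diet 2 splits did, the highest with 1076, which moved all 10 silica rats. On the high-fat diet 1 split did, with a highest other count of 1126. Other splits for the time differences had a term for the time of sampling that the real fit lacked. Their counts are therefore not on equal terms with the real ones.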

How the results depend on the processing

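The covariate and the legacy dispersion were chosen after seeing the data, the other alternatives before. Counts not named here stayed within 1.5 times. With the ribosomal RNA share as a covariate the calls were 93 for diet in air and 169 for diet with silica at 3 months, 3870 for silica on the regular diet, 1 for diet in air, 27 for diet with silica and 23 for the interaction at 9 months, and 77 for the time difference on the regular diet. At 9 months the share follows the groups, and its ranges did not overlap in any silica or diet comparison. The adjustment there extrapolates a slope within groups, and the standard errors were wider. Under the covariate 3 named genes changed sign for diet in air at 9 months, none past the test. They were Rnr1 (-0.86), which says nothing since Rnr1 is part of the covariate, Sqle (-0.049) and Fasn (0.016). DESeq2 gave 730, 227, 1 and 348 calls for diet in air, diet with silica and the interaction at 3 months and the interaction at 9 months, and limma voom gave 956 for diet in air at 3 months and 264 for the interaction at 9 months. A fit of only the groups compared gave 761 and 59 for diet in air and with silica at 3 months, and 471 for the time difference on the regular diet. The cause was not tested. Of the gene list tests, 166 were called and 44 with an estimated correlation. The 3-month correlation between diets was 0.757 for genes with a mean log2 CPM of at least 1. Leaving out 1 rat gave 63 to 530 and 55 to 209 calls for diet in air and with silica at 3 months, 260 to 724 for diet with silica at 9 months, 72 to 274 for the interaction at 9 months, 667 to 1338 and 1115 to 1908 for the time differences on the regular and high-fat diets, and correlations of 0.661 to 0.738 and 0.822 to 0.865 at 3 and 9 months. Of the named genes' calls, 665 stayed the same and 248 weakened with the covariate, 737 and 179 with 1 rat left out, 824 and 48 in a fit of only the groups compared, and 914 and 2 with RLE size factors.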

Other observations

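Mast cell genes were among those higher with silica on the regular diet at 9 months, with the mast cell carboxypeptidase Cpa3 at 2.61 ± 0.29, Ms4a2 at 2.13 ± 0.32 and Tpsb2 at 2.43 ± 0.38 on the log2 scale, while Kit was at -0.60 ± 0.09. The list, with 3 of 6 genes higher and 1 lower, was not called (adjusted p = 0.31). T and NK cell genes rose in 11 of 18 and fell in 3 there, with Foxp3, the regulatory T cell factor, at 2.15 ± 0.33, and that list was not called either (adjusted p = 0.085).

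A set of 15 liver genes, written after the files were seen, summed to 1886 CPM relative to the raw total count, without TMM scaling, in regular-diet air rat 3 at 9 months and at most 710 in every other rat. Without that rat the counts of calls at 9 months stayed within 1.5 times of those given.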
